A study of Homo sapiens with 4 samples.

How the data were processed

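Gene-level values of 4 RNA-seq libraries of the breast cancer cell line SUM159 were analysed, 2 from cells given DMSO and 2 from cells given doxycycline to induce a small interfering RNA against SHARP (SPEN). RNA came from total extracts and the libraries were made from polyadenylated RNA with a standard Illumina protocol, per the labels' protocols, although abundant RNAs without a poly(A) tail were present in the counts. The authors deposited estimated counts per gene symbol, not normalised and not all whole numbers, for 23394 genes. Reads were aligned with STAR and the genome build was GRCh37, per the submitters' processing notes. The program that counted reads per gene, its handling of ambiguous reads, the annotation and the use of strand are not given in the sources used here. Values differed from a whole number by more than 0.01 in 591 genes, 467 of them among the genes tested. Some ambiguous reads may have been divided between genes, which could not be checked. For genes with near-identical relatives, overlapping genes and antisense partners, the assignment of reads is therefore uncertain.

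Each of the 4 columns was matched to its sample by name, 0 columns of sample values were left unused, and groups were taken from the treatment labels. Estimated counts were rounded to whole numbers. The total per library was 16505321 and 17197715 in the controls and 15728387 and 15641296 in the knockdown. The 10 most abundant genes took 9.29% to 9.52% of the counts of a library. At these depths a floor of 3 counts corresponds to 0.172 to 0.195 CPM in a single library and to 0.0877 CPM over the 2 control libraries. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. The chi-square per gene and degree of freedom was 2.06 between the control libraries and 1.74 between the knockdown libraries. Duplicated reads alone could give such values, so this does not show that replicates are separate cultures, and libraries were kept separate as labelled. Values between groups gave 31.8 to 32.3.

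The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, glmQLFit and glmQLFTest, two-sided) with TMM scaling, group as the single term and genes kept by filterByExpr (minimum count 10). TMM factors were 1.02 and 1.01 in the controls and 0.983 and 0.986 in the knockdown. Of 18912 genes with a count, 13915 were tested. P-values were adjusted over all tested genes with the Benjamini-Hochberg method and called at 0.05. The biological coefficient of variation was 2.69%, so small fold changes passed the test. Fold changes against a group with 0 counts were computed against 3 counts over the group. CPM values are TMM-scaled unless stated otherwise, with the SD of 2 libraries.

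The design, the tests, 28 gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. The rule names SPEN, the 8 largest rises and the 8 largest falls among called genes with a mean CPM of at least 5 in the higher group and groups that do not overlap, leaving out unnamed loci. It also names up to 4 called members of each list with the smallest adjusted p, and HES1, HEY1, CD44, ALDH1A1 and ALDH1A3 in any case. Values of some genes that the rule names are not reported here. Other genes named because few members of a list moved were chosen after their values were seen. A total of 24 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. For each list, calls were also counted with p-values adjusted over the list alone.

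The first set of alternatives was RLE, upper-quartile and library-size scaling, no low-count filter, a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, a 2-fold threshold and an adjusted p under 0.01. Added after the data were seen were a correction for GC content and transcript length with splines of 5 degrees of freedom, leaving out genes with fractional counts, leaving out genes with GAAAGAA in the 3′ UTR, leaving out those and the genes without a searched 3′ UTR, testing the SPEN and RBPJ list without SPEN, and edgeR's glmTreat against a fold of 1.2. Gene names, transcript sequences and 3′ UTRs came from a GRCh38 reference (RefSeq names and GENCODE models), which is not the build of the counts, so no coordinates are given. Of the gene symbols, 22470 matched a current or older symbol, and 96.3% of tested genes had a GC content and a length.

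The main test was run on simulated counts with 200 genes changed, drawn from the means and library sizes of the real libraries for this comparison (13883 genes tested). It recovered 26.5% of genes changed 1.2-fold, 60% of those changed 1.5-fold, 96% of those changed 2-fold and 93.9% of those changed 4-fold. Of 141 calls, 2.8% were false, and 0 of 50 unchanged lists were called. Genes were drawn independently and those lists were random, so the simulation does not show how camera fares on lists whose members vary together. With few genes changed, the adjustment was also stricter than in the real data, so recovery by the real test may differ.

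Every 7-base sequence in 3′ UTRs was scored, in the longest transcript with a 3′ UTR of at least 50 bases, for 12430 tested genes (89.3%). The log2 fold change, limited to 2 in either direction, was regressed on the presence of the sequence with cubic terms for 3′ UTR length, GC content and expression (numpy 2.4.6). In 10 simulations with shuffled fold changes and a known effect of 0.1 on the log2 scale, the sequence was recovered as the strongest in 10. Without an effect the ratio defined with that test reached 1.14 at most. Shuffling removes every link between sequence and fold change. The simulations therefore do not tell silencing through a seed from other changes tied to sequence. Intervals of medians and means of lists are 95% bootstrap intervals over genes (10000 draws).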

Results

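RNA was sequenced from SUM159, a mesenchymal-like triple-negative breast cancer cell line, in libraries described as made from polyadenylated RNA. There were 2 control libraries from cells given DMSO, the solvent control, and 2 libraries from cells given doxycycline to switch on a small interfering RNA against SHARP. SHARP is an alias of SPEN, a large RNA-binding corepressor that joins the Notch effector RBPJ to histone deacetylase complexes. The libraries held 16505321 and 17197715 counts in the controls and 15728387 and 15641296 in the knockdown, with 17237 to 17308 genes detected in each. The comparison asks which transcripts differ in these breast cancer cells once SPEN is lowered, the series being concerned with SPEN as a scaffold of epigenetic regulation in breast cancer stem cells. Values below are TMM-scaled CPM given as mean ± SD of the 2 libraries of a group, and log2 fold changes are knockdown over control.

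SPEN itself fell from 185 ± 1.84 CPM in the controls to 108 ± 0.443 CPM in the knockdown (n = 2 each), which left 0.582 times the control level. Its counts were 3129 and 3208 in the control libraries and 1660 and 1666 in the knockdown libraries. The log2 fold change was -0.78 (SE 0.035), with an adjusted p of 1.39e-10 in edgeR's quasi-likelihood test. Transcripts of the proteins that work with SPEN moved less. Of 21 measured genes of the SPEN and RBPJ corepressor complex, SPEN included, 12 fell and 3 rose, the same counts as adjusted over the list alone. CIR1, a corepressor that binds RBPJ, fell by 0.51 on the log2 scale, from 40.0 to 28.1 CPM. The histone H3K4 demethylase KDM5A fell by 0.34. The 3 that rose were TBL1XR1 (0.14), HDAC2 (0.13) and KDM1A (0.091). As a set the complex was not past the threshold of camera (median log2 fold change -0.12, adjusted p = 0.0991, and adjusted p = 0.440 with an estimated correlation). Without control replicate 2 its camera adjusted p was 0.0463, and with scaling by library size alone it was 0.0499. Those values rested on SPEN, since the other 20 genes, of which 11 fell, had a camera adjusted p of 0.211 and 0.214 under these settings and 0.319 with all libraries and TMM scaling (adjusted p = 0.592 with an estimated correlation). Among 8 measured genes of the SPEN paralogs and the m6A methyltransferase complex they belong with, WTAP (0.27), KIAA1429 (0.26) and CBLL1 (0.22) rose, and METTL14 (-0.27) and ZC3H13 (-0.13) fell, the same counts as adjusted over the list alone. That list was not called by camera (adjusted p = 0.644, and adjusted p = 0.713 with an estimated correlation), and CBLL1 had an edgeR quasi-likelihood adjusted p of 0.0558 without control replicate 2.

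The naming rule requires a mean CPM of at least 5 in the higher group. Under it the largest rises included INHBA, SULT1E1, DHRS2, HSD11B1, IL8, IL6, CSF3 and LAMB3, and the largest falls ITGA11, FIBIN and CYP4B1. The chemokine IL8 went from 14.1 ± 0.264 to 295 ± 10.6 CPM, a 21.0-fold rise, and LAMB3, a chain of the basement membrane protein laminin-332, from 23.1 ± 0.644 to 218 ± 2.95 CPM, a 9.42-fold rise (n = 2 per group). INHBA, which encodes the subunit of activin A, had 0 counts in both controls and 117 and 116 counts in the knockdown. Set against a floor of 3 counts over the control group, INHBA was at least 86.1-fold higher. The edgeR quasi-likelihood adjusted p was 2.44e-17 for IL8, 4.39e-16 for LAMB3 and 2.61e-09 for INHBA.

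The other large rises began from few counts. SULT1E1, the estrogen sulfotransferase, had 3 and 2 counts in the controls and 113 and 112 in the knockdown (log2 fold change 5.57, SE 0.32). DHRS2, a short-chain dehydrogenase, rose by 5.13 (SE 0.26), and HSD11B1, which regenerates active glucocorticoid, by 4.72 (SE 0.34). The cytokines IL6 and CSF3 rose by 4.25 (SE 0.29) and 3.85 (SE 0.28), to 8.46 ± 1.04 and 6.42 ± 0.540 CPM. The edgeR quasi-likelihood adjusted p of these 5 genes was at most 2.52e-08.

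The largest falls under the naming rule were smaller than the largest rises. ITGA11, a collagen-binding integrin chain, went from 8.06 ± 1.5 to 1.26 ± 0.506 CPM, and FIBIN from 7.42 ± 0.209 to 1.17 ± 0.0898 CPM (log2 fold change -2.66 for both). The cytochrome P450 gene CYP4B1 fell by 2.40, the cadherin CDH6 by 2.18 and the platelet-derived growth factor receptor PDGFRB by 1.89. AKR1C2 (-2.15) and AKR1C3 (-2.14), aldo-keto reductases of steroid hormones, and the pregnancy-specific glycoprotein PSG4 (-2.12) also fell. These 3 genes have near-identical relatives, so how reads were assigned among the copies is uncertain. The highest edgeR quasi-likelihood adjusted p among these 8 genes was 8.70e-06, for PSG4. Outside the rule, the called gene TMX2-CTNND1 had no counts in the knockdown libraries. It was at least 25.6-fold lower against a floor of 3 counts over the knockdown group.

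**Figure D1:**
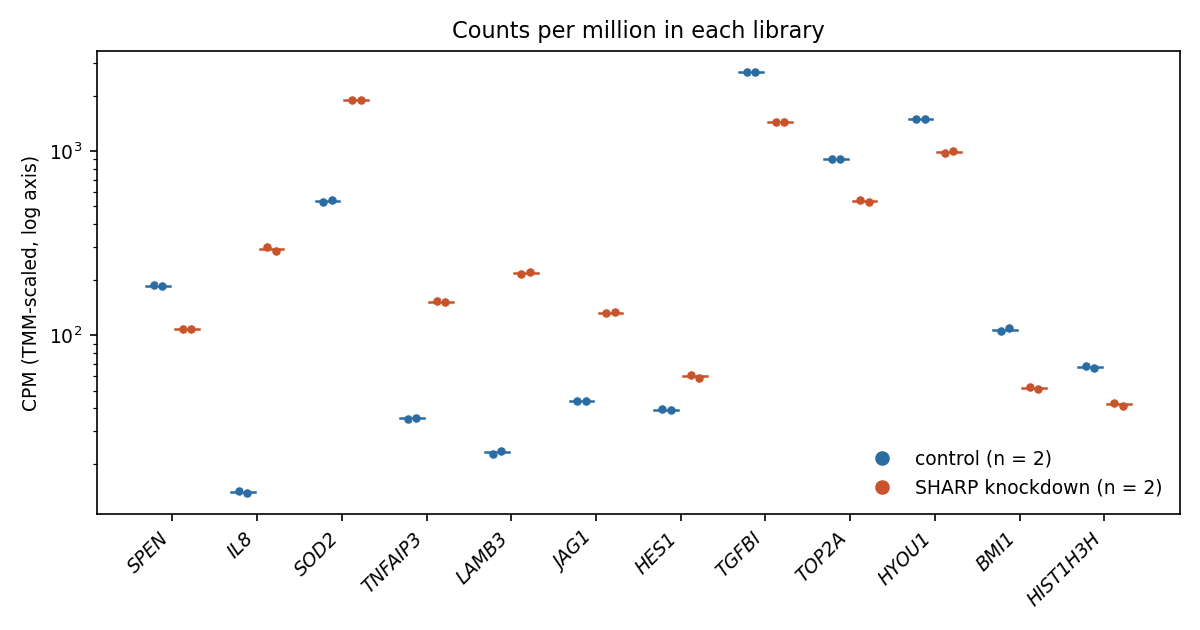
TMM-scaled CPM (log axis) of 12 named genes in each library, with control libraries in blue, knockdown libraries in orange and horizontal bars at the group means (n = 2 per group). SPEN lay at 185 CPM in the controls and 108 in the knockdown, while IL8 lay at 14.1 and 295 CPM.

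In all, 6970 of 13915 tested genes (50.1%) had an adjusted p under 0.05 in edgeR's quasi-likelihood test, 3499 higher and 3471 lower in the knockdown. Most of these changes were small. The median size of the log2 fold change of called genes was 0.34, 47.5% of them differed by less than 1.25-fold, and 301 rose and 277 fell by at least 2-fold. Against a fold change of at least 1.2, edgeR's test called 1216 higher and 1305 lower, a threshold added after the data were seen. Replicates lay close together, with a median absolute log2 difference of 0.072 in the controls, 0.075 in the knockdown and about 0.23 between libraries of different groups. The groups did not overlap for 74.3% of the tested genes, where chance alone gives 33.3%. The 7-base sequence GAAAGAA, picked for its link to these same fold changes, occurred in the 3′ UTR of 32.2% of the lower genes, 21.7% of the higher genes and 22.0% of the genes not called, among 12430 tested genes with an annotated 3′ UTR. Doxycycline was given only to the knockdown cells, so an effect of the drug and an effect of the knockdown are not separated by these 4 libraries, and whether the control cells carried the construct is not given in the sources used here. The replicates are not stated to be separate cultures, and the p-values then measure the spread between these libraries, which may be technical.

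**Figure D2:**
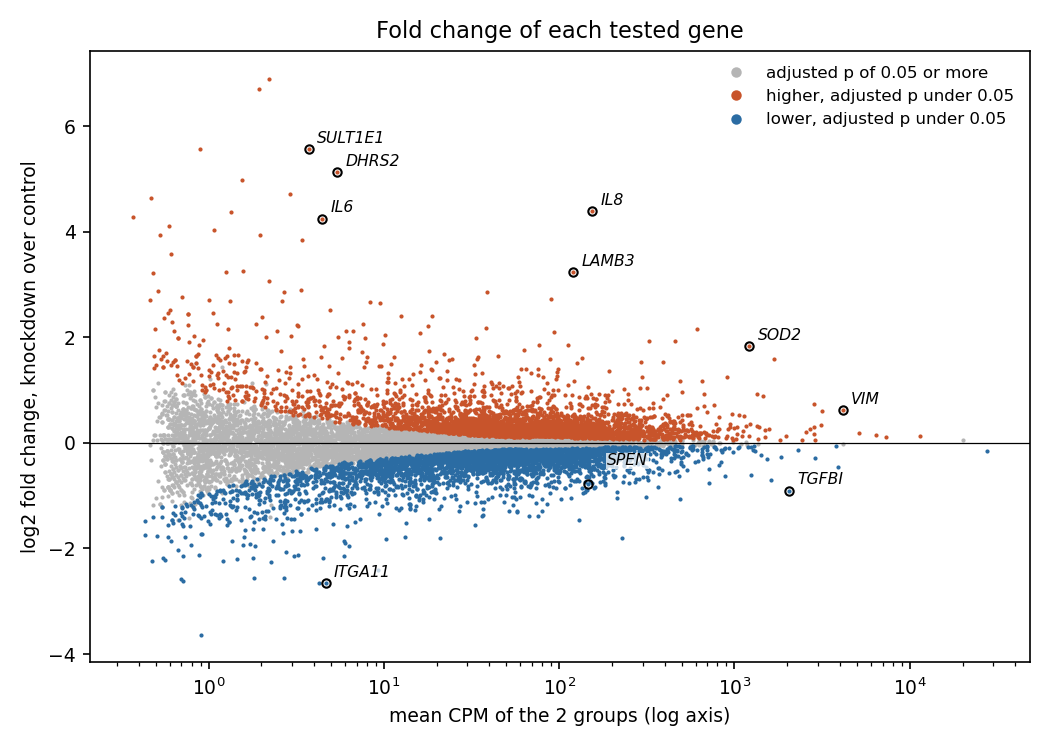
Log2 fold change of each tested gene (vertical axis, knockdown over control) against its mean CPM over both groups (log axis), coloured by the edgeR call, with 10 genes circled. The 4 tested genes with 0 counts in 1 group, INHBA among them, are left out, and IL8 lies at 4.39 and ITGA11 at -2.66.

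Of 22 measured genes of NF-kB signalling and its cytokines, 20 rose and 1 fell, the same counts as adjusted over the list alone, with a median log2 fold change of 1.53. Camera placed the list above the other tested genes (adjusted p = 2.61e-44, and adjusted p = 0.168 with an estimated correlation). Besides IL8, the mitochondrial superoxide dismutase SOD2 went from 533 ± 9.52 to 1895 ± 2.54 CPM, a 3.55-fold rise. TNFAIP3, which encodes the feedback inhibitor A20, rose 4.31-fold from 35.3 ± 0.392 CPM, and the inhibitor of apoptosis BIRC3 1.95-fold from 340 ± 0.982 CPM. The edgeR quasi-likelihood adjusted p of these 3 genes was at most 9.56e-13. The member that fell was TNFAIP2 (-0.30), and CCL5 had a log2 fold change of 0.18 that did not pass the test. Members of lists named for belonging to a small count, such as these, were chosen after their values were seen. The leukocyte markers summed to 37.1 and 41.1 CPM in the control libraries and 47.5 and 48.8 CPM in the knockdown.

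Target genes of YAP and TEAD, TGF-beta and SMAD targets and basal breast genes were also higher as sets in camera at the preset correlation. The camera adjusted p was 1.34e-08 for YAP and TEAD targets, 0.0112 for TGF-beta targets and 3.25e-04 for basal genes (adjusted p = 0.268, 0.342 and 0.307 with an estimated correlation). For basal genes it was 0.197 without the low-count filter and 0.0970 with limma-voom. Among 22 YAP and TEAD targets, 16 rose and 4 fell (AMOTL2, ARHGEF17, RBMS3 and IGFBP3). The matricellular protein genes CTGF and CYR61 rose 5.28-fold and 1.68-fold, NT5E, the ectonucleotidase CD73, rose 2.53-fold and CRIM1 1.44-fold. Among 18 TGF-beta and SMAD targets, 10 rose and 2 fell. BAMBI, a decoy receptor of the pathway, rose from 13.8 ± 0.836 to 62.3 ± 0.326 CPM, and JUNB (0.84) and ID1 (0.65) rose as well. TGFBI went the other way, from 2680.2 ± 15.8 to 1435 ± 4.22 CPM. Of 11 basal breast genes, 6 rose and 2 fell. The growth factor receptor EGFR rose 1.39-fold, while the hemidesmosome integrin ITGB4 fell from 110 ± 0.542 to 42.1 ± 4.28 CPM and CAV1 by 0.17. Counts for these 3 lists were the same when adjusted over the list alone.

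Of 14 measured Notch target genes, 7 rose and 2 fell, with a median log2 fold change of 0.13 and the same counts as adjusted over the list alone. Camera called the set higher at the preset correlation (adjusted p = 0.00434, and adjusted p = 0.440 with an estimated correlation), but not without the low-count filter (adjusted p = 0.0840) or with limma-voom (adjusted p = 0.0850). The transcription factor HES1, a direct target of the pathway, rose from 39.3 ± 0.423 to 59.7 ± 1.88 CPM (log2 fold change 0.60, SE 0.046, edgeR quasi-likelihood adjusted p = 5.90e-08). The ligand JAG1 rose 3.01-fold to 132 ± 1.58 CPM, MYC 1.41-fold to 1332 ± 1.30 CPM and the cytokine receptor IL7R 4.80-fold to 12.5 ± 0.753 CPM. The 2 that fell were NOTCH3 (-0.46) and CCND1 (-0.062). HEY1, another target, was at 1.73 ± 0.0889 and 1.23 ± 0.460 CPM and did not pass the test (adjusted p = 0.234 in edgeR's quasi-likelihood test). Several leading members are shared with other lists, since JAG1 is also a ligand and MYC also a Wnt target. Among 20 receptors, ligands and processing genes, 4 rose, among them JAG1, MAML2 and MAML3, and 6 fell, among them NCSTN (-0.60), a gamma-secretase subunit, again the same counts as adjusted over the list alone. The camera adjusted p was 0.732 for the receptors and ligands (adjusted p = 0.881 with an estimated correlation), whose median log2 fold change was -0.057 while their mean was 0.033 and the camera direction was up.

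Of 17 measured genes used to mark breast cancer stem cells, 8 rose and 3 fell, the same counts as adjusted over the list alone. KLF4 rose from 70.9 ± 1.56 to 101 ± 4.24 CPM and CD44 from 384 ± 7.52 to 428 ± 0.158 CPM, a 1.11-fold difference. ALDH1A1 rose from 2.04 ± 0.357 to 4.44 ± 0.0389 CPM, whereas ALDH1A3 was at 1.62 ± 0.582 and 1.13 ± 0.231 CPM and did not pass the test. The Polycomb gene BMI1 fell from 107 ± 2.42 to 51.4 ± 0.882 CPM, ITGA6 from 144 ± 6.6 to 105 ± 1.72 CPM and CD24 by 0.91 on the log2 scale. The edgeR quasi-likelihood adjusted p was 3.19e-10 for BMI1, 4.99e-05 for CD44, 5.25e-04 for ALDH1A1 and 0.249 for ALDH1A3. The sequence GAAAGAA was in the 3′ UTR of 9 of the 17 genes, against 24.6% of all searched genes. BMI1 had 1 site and ITGA6 3, but CD44, with 3, and ALDH1A1, with 1, rose. BMI1 is also among the genes whose deposited values were not all whole numbers. Camera did not place the list above other genes (adjusted p = 0.319, and adjusted p = 0.536 with an estimated correlation), whereas fry, which tests against no change, called it higher (adjusted p = 0.0197).

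Genes of the epithelial to mesenchymal axis moved in both directions. Of 23 mesenchymal genes, 10 rose and 7 fell, and 11 rose when adjusted over the list alone. Vimentin (VIM) rose from 3257 ± 2.99 to 5020 ± 55.2 CPM, the receptor kinase AXL 1.33-fold and the matrix protein SPARC 1.44-fold, against the fall of TGFBI. Of 25 epithelial genes, 9 had enough counts to be tested, and CDH1, GRHL2 and KRT19 had 0 counts in every library. Among the 9, the keratins KRT7 (0.28) and KRT8 (0.29) rose and the splicing factors ESRP1 (-1.18) and ESRP2 (-0.40) and the junction protein JUP (-0.91) fell. Of 10 luminal genes, 3 rose (KRT8, CA12 at 0.28 and XBP1 at 0.13) and 2 fell, among them GATA3 (-0.60). Epithelial and luminal counts were the same when adjusted over the list alone. None of the 3 lists was called by camera, with adjusted p of 0.543, 0.812 and 0.812 (adjusted p = 0.713, 0.881 and 0.882 with an estimated correlation). The epithelial list, down in camera, was up under 4 other settings, and the luminal list had a median of -0.037 and a mean of -0.065 with an upward camera direction.

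Of 34 genes of G2 and mitosis, 27 fell and 1 rose (ECT2), and 28 fell when adjusted over the list alone. The median log2 fold change of the list was -0.38, and its camera adjusted p was 7.48e-13 (adjusted p = 0.307 with an estimated correlation). TOP2A, the mitotic topoisomerase, went from 906 ± 1.81 to 534 ± 9.30 CPM, the proliferation antigen MKI67 from 633 ± 13.7 to 441 ± 6.65, the kinetochore gene CENPF from 552 ± 0.998 to 383 ± 11.3 and the kinesin KIF4A from 73.9 ± 0.155 to 38.8 ± 0.519. Of 24 replication-dependent histone genes, 19 fell and 1 rose (HIST1H1D), and 2 rose when adjusted over the list alone. Their median was -0.33, with a camera adjusted p of 7.70e-05 (adjusted p = 0.440 with an estimated correlation). HIST1H3H fell by 0.68 on the log2 scale, HIST1H2AG by 0.57, HIST1H2BK by 0.49 and HIST1H3B by 0.40. Histone genes share near-identical coding sequence, so single members are uncertain, and their mRNAs mostly lack a poly(A) tail, which the library method is stated to select for. The 9 tested RNAs of other classes that lack a poly(A) tail had a median log2 fold change of 0.40. Among them RPPH1 lay at 10864 CPM and RMRP at 4825 CPM in the controls, against 4163 CPM for GAPDH, so the libraries held much RNA of this kind in spite of the stated selection. These 3 genes were chosen after their values were seen.

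Genes of S phase and E2F were divided. Of 40 measured genes, 14 fell and 8 rose, and 15 fell when adjusted over the list alone. The replication licensing factor CDC6 fell from 49.5 ± 0.0840 to 29.2 ± 1.15 CPM, CLSPN by 0.63 and TK1 by 0.55, while the helicase subunit MCM7 rose by 0.32. Camera did not call the list (median -0.091, adjusted p = 0.319, and adjusted p = 0.499 with an estimated correlation). Fry, which tests against no change, called it lower (adjusted p = 0.00395).

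Of 19 genes of the unfolded protein response, mostly chaperones and folding enzymes of the endoplasmic reticulum, 17 fell and 2 rose (DNAJB9 and XBP1), the same counts as adjusted over the list alone. The camera adjusted p of the list was 1.11e-08 (adjusted p = 0.307 with an estimated correlation). HYOU1 went from 1494 ± 5.82 to 983 ± 17.6 CPM and HSPA5, the chaperone BiP, from 934 ± 6.25 to 698 ± 7.39 CPM. The degradation factors EDEM1 and HERPUD1 fell by 0.42 and 0.49 on the log2 scale. Of 31 genes of the integrated stress response, 16 fell and 7 rose, the same counts as adjusted over the list alone. NUPR1 (-1.38) and TRIB3 (-0.50) fell, and the glycyl-tRNA synthetase GARS (0.37) and STC2 (0.53) rose. Camera did not call that list (adjusted p = 0.0777, and adjusted p = 0.405 with an estimated correlation), but did so with library-size scaling (adjusted p = 0.0180) and without the low-count filter (adjusted p = 0.0326).

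Of 30 glycolytic and hypoxia-linked genes, 17 rose, 3 fell and 10 did not pass the test, the same counts as adjusted over the list alone. The camera adjusted p was 0.00233, upward (adjusted p = 0.342 with an estimated correlation). Enolase (ENO1) rose from 868 ± 19.8 to 1257 ± 24.6 CPM and the phosphofructokinase PFKP 1.58-fold. The glucose transporter gene SLC2A1 fell from 124 ± 1.19 to 68.4 ± 0.978 CPM, VEGFA from 288 ± 4.75 to 201 ± 1.05 CPM and BNIP3 by 0.24 on the log2 scale. Of 38 nuclear genes of oxidative phosphorylation, 17 rose and 1 fell (NDUFS8), by small amounts, as in UQCRFS1 (0.49), UQCRC2 (0.38), ATP5A1 (0.26) and ATP5B (0.18), with the same counts as adjusted over the list alone. That list had a camera adjusted p of 0.110 (adjusted p = 0.713 with an estimated correlation), which became 0.0163 without control replicate 2, 0.0172 with limma-voom and 0.00807 without the low-count filter. Of 20 genes of cholesterol synthesis, 10 rose and 3 fell, again the same counts as adjusted over the list alone. SQLE (0.52), CYP51A1 (0.33) and INSIG1 (0.55) rose, while STARD4 (-0.79) and EBP (-0.26) were among those that fell. Camera did not call it (adjusted p = 0.670, and adjusted p = 0.713 with an estimated correlation).

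Interferon response, p53, Wnt and chromatin-modifier genes were not set apart from other genes by camera. Of 28 interferon response genes, 8 fell and 4 rose (SAMD9L, DDX58, IFIH1 and DTX3L), with BST2 (-0.49), STAT2 (-0.47) and PARP9 (-0.37) among those that fell. Of 24 p53 targets, 7 rose, including AEN (0.72) and GADD45A (0.38), and 7 fell, including the ribonucleotide reductase subunit RRM2B (-1.02) and ZMAT3 (-0.71). The p53 list had a median of 0.044, a mean of -0.077 and a downward camera direction. Of 13 Wnt targets, 4 rose (MYC, DKK1, CD44 and AXIN2) and 5 fell (CCND1, ZNRF3, LEF1, RNF43 and APCDD1), and 5 rose when adjusted over the list alone. DKK1, a secreted Wnt inhibitor, rose 6.54-fold from 0.352 CPM, and AXIN2 had an edgeR quasi-likelihood adjusted p of 0.0522 without control replicate 2. The Wnt list had a median of -0.14, a mean of 0.027 and an upward camera direction. Of 39 histone and DNA modifiers, 9 rose, including HDAC9 (1.21), JARID2 (0.81) and the remodeller ATPase SMARCA4 (0.29), and 9 fell, BMI1 the most, with a median of 0.010, a mean of -0.0093 and a downward camera direction. Except for the Wnt list, these counts were the same when adjusted over the list alone. The camera adjusted p of the 4 lists was 0.495, 0.697, 0.640 and 0.812 in the order given (adjusted p = 0.635, 0.723, 0.713 and 0.881 with an estimated correlation). Against no change, fry called the interferon and p53 lists lower (adjusted p = 0.0213 and 0.0197) and the Wnt list higher (0.00619), and did not call the chromatin modifiers (0.726).

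**Figure D3:**
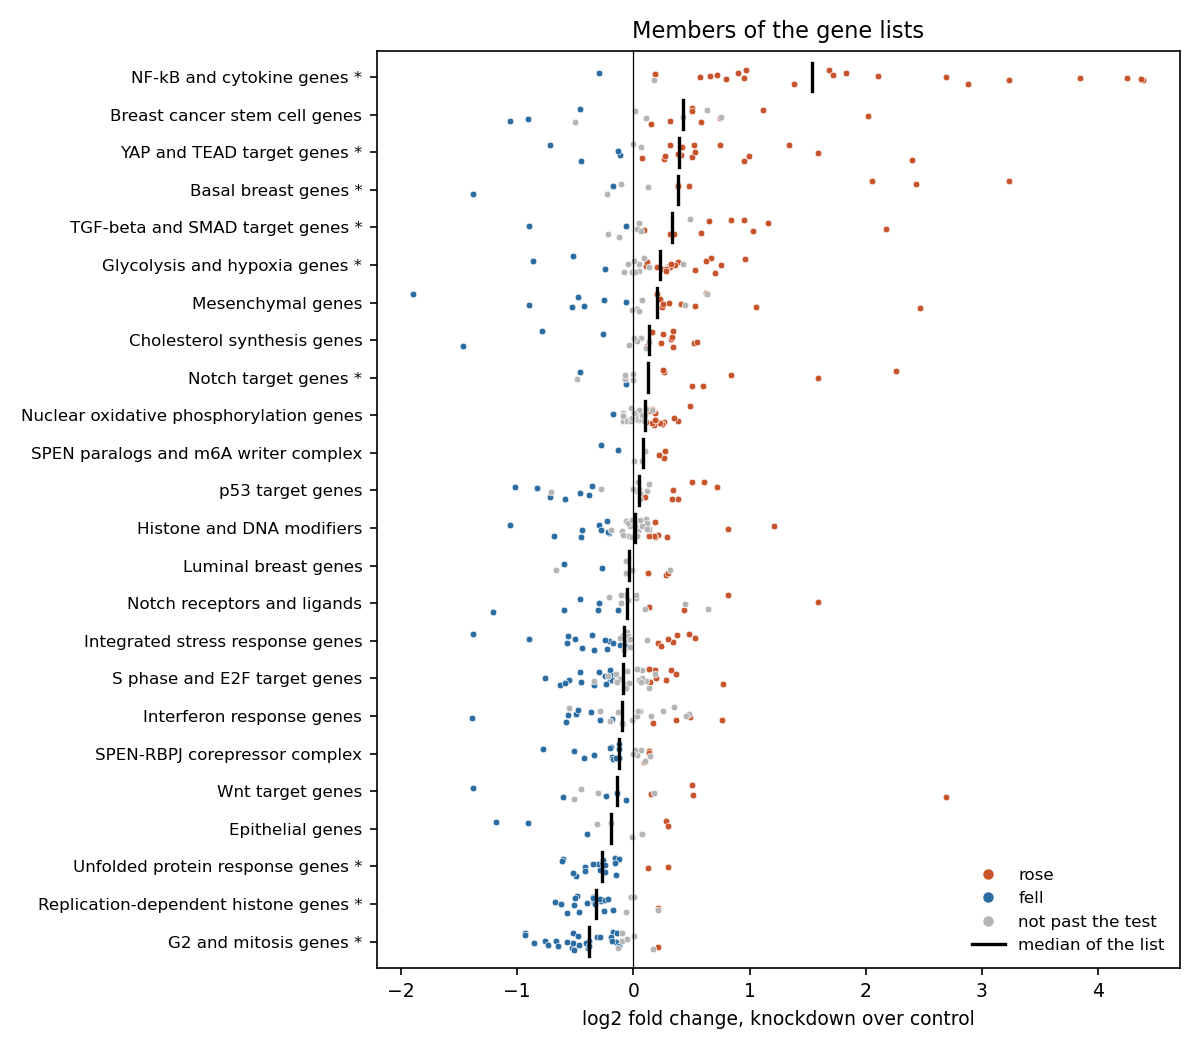
Log2 fold change (horizontal axis, knockdown over control) of each tested member of the 24 lists with at least 5 tested genes, orange where it rose, blue where it fell and grey where it did not pass edgeR's test, with a black bar at the list's median. Asterisks mark the 9 lists called by camera at the preset correlation, from NF-kB and cytokine genes (median 1.53) to genes of G2 and mitosis (median -0.38).

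Markers of other cell types were low or sparse, as far as these lists reach. Of 18 leukocyte markers, 4 were tested and 2 rose, ITGAM and CD68, the same count as adjusted over the list alone. ITGAM had 0 counts in the controls and 10 and 19 in the knockdown, at least 10.7-fold higher against the floor of 3 counts over the control group. CD68, a lysosomal protein also made outside the blood, rose 1.24-fold from 31.4 ± 3.23 CPM (edgeR quasi-likelihood adjusted p = 0.00132, and 0.0703 without control replicate 1). The median of the 4 was 0.24, with ITGAM at its bound as well. Of 10 endothelial markers 2 were tested and ERG rose 1.65-fold, and of 13 melanocyte and neural markers 3 were tested and MITF fell from 20.5 ± 1.58 to 6.0 ± 0.605 CPM, with the same counts as adjusted over the list alone. The 13 mitochondrially encoded genes were not analysed here.

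Across the 24 lists tested by camera, 6 were higher and 3 lower at the preset correlation of 0.01. With an estimated correlation 0 lists passed after adjustment and 2 had an unadjusted p under 0.05, in a design with 2 residual degrees of freedom. Fry called 19 lists for a balance of movement in 1 direction and 24 for change in either direction, and it does not compare a list with other genes. Lists that fry but not camera called lower were the SPEN and RBPJ complex, S phase, integrated stress response, interferon and p53. Those that fry alone called higher were the SPEN paralog and m6A, Wnt, stem cell, mesenchymal and cholesterol lists.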

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

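The GC and length correction, the settings without genes with fractional counts, with GAAAGAA in the 3′ UTR or without a searched 3′ UTR, and the test against a 1.2-fold change were chosen after the data were seen. SPEN was lower under every setting tried, with a log2 fold change of -0.83 to -0.77, and between -0.79 and -0.77 with a library left out. Named genes were followed under 16 alternative settings, without the thresholds of fold change or the stricter adjusted p. Of 1691 values of 110 named genes there, 1688 kept their direction and their side of the threshold and 0 changed sign. The 3 others, each with a smaller control group, were CD68 without control replicate 1 and CBLL1 and AXIN2 without control replicate 2. Most named genes were picked for large fold changes or small adjusted p in these same libraries. Their stability therefore does not speak for all genes. Of the 6970 calls of the main test, limma-voom shared 6854 in the same direction and DESeq2 4965. With 1 library left out, the lone library of its group was assumed to vary like the others. The count of higher genes was then 2607 to 3220, of lower genes 2430 to 3122, of higher lists 6 to 7 and of lower lists 3 to 4.

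Thresholds of size moved the counts most. At least 2-fold changes were 301 higher and 277 lower, and the test against a 1.2-fold change called 1216 higher and 1305 lower, by construction of those thresholds. DESeq2 called 2601 higher and 2364 lower genes, and scaling by library size alone 2966 and 4101, which put 42.0% of calls on the higher side in place of 50.2%. That scaling moved the median log2 fold change of all tested genes by -0.046, the largest shift of any scaling. Library-size scaling called 5 lists lower, with the integrated stress response and the SPEN and RBPJ complex added, the latter at 0.214 once SPEN was left out. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry called 11 higher and 8 lower. In the other 15 settings NF-kB, YAP and TEAD, TGF-beta, glycolysis, mitosis, unfolded protein response and histone lists kept their calls in 15, and the basal and Notch target lists in 13, the exceptions being no low-count filter and limma-voom. The cause was not tested.

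The replicate number fitted as a replicate block gave 3609 higher and 3602 lower genes and changed no call of a list. Same-numbered libraries are not stated to share a day or culture, and with 2 pairs their deviations correlated across genes at a Pearson r of 0.19 and a Spearman rho of -0.027. Depth limits the genes near the floor of 3 counts. In the simulation 1.2-fold changes were recovered in 26.5% of cases. With 200 genes changed there and 6970 called in the real data, the simulated adjustment was stricter, so this is not the recovery of the real test.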

Other observations

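The tests of hormone, ERK, secretory and deacetylase lists, of 7-base sequences, of GC and length, of RNAs without a poly(A) tail, of S phase genes as an explanation and of leukocyte genes without LAPTM5 were chosen after the results above had been seen.

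Immediate outputs of ERK signalling were mostly higher in the knockdown. Of 14 measured genes, 10 rose and 3 fell. The feedback inhibitor SPRY4 went from 135 to 267 CPM, IER3 from 43.6 to 107 CPM, PHLDA1 from 46.3 to 91.0 CPM and the phosphatase DUSP6 from 8.27 to 15.2 CPM. EGR1, an immediate early gene, fell from 45.3 to 22.7 CPM, and ETV5 (-0.44) and SPRED2 (-0.19) fell as well. The mean log2 fold change was 0.34 (95% interval 0.022 to 0.63), and camera gave an adjusted p of 0.00131 over 4 such lists (adjusted p = 0.213 with an estimated correlation). Higher ERK activity is a hypothesis that may account for the 10 genes that rose, and the 3 that fell stay outside it. It rests on this list alone, since ERK itself was not measured here.

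Other secreted and hormone-responsive genes also moved. The epidermal growth factor receptor ligands EREG (66.7 to 203 CPM) and AREG (1.29 to 2.88 CPM) rose, and so did 4 others of 9 genes of a senescence-associated secretion list made without the NF-kB genes, while TIMP2 and FGF2 fell. Its mean was 0.38, with an interval of -0.012 to 0.81 (camera adjusted p = 0.0121, and adjusted p = 0.213 with an estimated correlation). The metallothioneins MT2A, MT1E and MT1X and TUBB3 rose among 8 genes that deacetylase inhibitors raise, and CLU and H1F0 fell. That list's mean was 0.29, with an interval of -0.13 to 0.70 (camera adjusted p = 0.0121, and adjusted p = 0.213 with an estimated correlation). A senescence-like secretory state and weaker deacetylase repression could be read from these calls. The metallothioneins belong to the same gene family, so their rises may not be independent. The cell-cycle inhibitor CDKN1A, which is in neither list, was at 42.8 CPM in both groups (edgeR quasi-likelihood adjusted p = 0.991). Both lists met the prediction written in advance, a camera adjusted p under 0.05 over the 4 lists, at the preset correlation. Both explanations are still left open, because both intervals include 0, a bound that was set after the values were seen. Among 11 glucocorticoid-induced genes, in cells grown with hydrocortisone, 6 rose and 4 fell. SGK1 (1.24), DUSP1 (1.04), ERRFI1 (0.92), RGS2 (0.62), PER1 (0.37) and ZBTB16 (0.10) rose, and TSC22D3 (-0.58), KLF9 (-0.36), FKBP5 (-0.17) and GLUL (-0.14) fell. Their mean of 0.27 (95% interval -0.058 to 0.61, camera adjusted p = 0.139) does not decide whether receptor activity differed.

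The 7-base sequence most strongly tied to lower values in the knockdown, when present in the 3′ UTR, was GAAAGAA. It went with a log2 fold change lower by 0.10 (t = -9.68, 3056 of 12430 genes), against a most positive t of 3.99 among 15589 sequences, and it was the leading sequence in each of 2 random sets of 6215 genes (t = -7.24 and t = -6.48). In all, 5 sequences had a negative t larger in size than 3.99. AGAAAGA (-6.77), AAAGAAA (-5.79) and TGAAAGA (-5.77) share 6 bases with GAAAGAA, while GGTAAGT (-4.47) does not and kept a t of -4.24 among genes without GAAAGAA. The adjusted mean log2 fold change was 0.019 with 0 sites, -0.031 with 1, -0.093 with 2 and -0.15 with 3 or more. Followed by A, as in GAAAGAAA, the difference was -0.14 (t = -10.8), and followed by C, as in GAAAGAAC, it was -0.032 (t = -1.61). The sequence does not sort single genes. Of the named genes with a searched 3′ UTR, it was in 19 of 46 that fell (NUPR1 with 30 sites, MITF with 6 and CDH6 with 3) and in 12 of 61 that rose (HDAC9 with 5, IL7R with 4 and CD44 with 3).

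A candidate explanation is silencing of other genes through the seed of the small interfering RNA, whose sequence is not known here. The prediction written in advance was a most negative t at least 1.5 times the size of the most positive, and the ratio was 2.43. Purine-rich composition is argued against by the 20 other arrangements of the same letters, whose median t was -1.13. The lowest, AGAAAGA, had a t of -1.84 among the 9374 searched genes without GAAAGAA. Repeats of GAAA are argued against by genes without GAAAGAAAG, in which the difference was still -0.09 (SE 0.011), though NUPR1 and MITF do hold that repeat. GAAAGAA in the coding part also went with lower values (-0.062, t = -6.09), so the association is not confined to 3′ UTRs, and a protein that binds the sequence was not tested. Without the genes that carry it in the 3′ UTR 2592 genes were higher and 2525 lower, with 6 and 3 lists called. Leaving out genes without a searched 3′ UTR too gave 2508 and 2384 and the same lists. Both settings take out only genes that could be silenced directly through a 3′ UTR site. Any secondary effects, and genes with the sequence in the coding part alone, stay in. How much of the change comes from such silencing is therefore not shown.

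For the rise of NF-kB and cytokine genes, RNA from leukocytes was tested with 13 genes abundant in those cells. Their sum rose by 1.47 CPM against 281 CPM for IL8 alone, from 8.45 ± 0.0261 to 9.92 ± 3.96 CPM, which argues against it, and LAPTM5, which fell from 184 to 96.5 CPM, was left out of the sum and would turn it downward. A GC or length bias is argued against as well, since the list's median was 1.52 after correction and 1.53 before. Doxycycline itself cannot be told apart from loss of SPEN, because 0 libraries had the drug without the knockdown. Off-target silencing and the loss of SPEN both stay open as sources of the rise, and neither was separated by a second small interfering RNA in these libraries.

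For the fall of replication-dependent histone genes, less carry-over of RNA without a poly(A) tail could lower them. The 9 tested RNAs of that kind from other classes had a median log2 fold change of 0.40 (95% interval 0.14 to 0.59, 6 rose and 0 fell), opposite to the histone median of -0.33, and RPPH1 went from 10864 to 11933 CPM and RMRP from 4825 to 5489 CPM. At such levels the stated selection was incomplete or not made, and in either case these 9 RNAs were not scarcer in the knockdown as a set. Their median was the value of RNU11, which went from 1.37 to 1.81 CPM and did not pass the test. The abundant RPPH1 (0.14) and RMRP (0.19) rose by less. Carry-over of histone mRNA itself was not measured. A GC or length bias is argued against by a histone median of -0.35 after correction. Fewer cells in S phase may account for it and stays open, since the S phase and E2F list had a median of -0.091 (95% interval -0.19 to 0.055). Histone genes that share near-identical sequence make single members uncertain.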
